A study of Arabidopsis thaliana with 7 samples.

How the data were processed

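RNA sequencing libraries had been made from total RNA of Arabidopsis thaliana seedlings of the Col-0 accession, 12 days old, grown at 16 °C in long days and collected 4 h after lights on (ZT4). The labels give 3 wild-type (WT) libraries and 4 libraries of the glk1 glk2 double mutant, each named by genotype and replicate number. Libraries were prepared for DNA nanoball sequencing, per the labels' protocols. Nothing in the labels says that replicates came from separate plantings, so p-values measure the spread between these 7 libraries, which may be technical.

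The authors deposited 1 table of TPM values (transcript abundance scaled to a fixed total per library) with 27655 genes and 1 column per library. The tools TopHat2 and Cufflinks and the build TAIR10 are named, with no versions, per the submitters' processing notes. The annotation, strand setting, filters and treatment of reads shared between genes are not given in the sources used here. Each deposited TPM column sums to 1000000, so a TPM value is a share of the library and keeps no read depth. The depth behind each value is therefore unknown, and no counting interval is given. Of the gene identifiers, 27445 matched the locus tags of the RefSeq annotation of TAIR10.1, which was used for gene symbols, products, the order of genes along chromosomes and the positions of GLK1 and GLK2. The deposited table holds no coordinates.

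In the deposited table the column of WT replicate 1 is written in another row order than the gene identifiers and the other 6 columns. In 5606 rows the identifiers are not in alphabetical order, among them 4832 of the 5460 rows of chromosome 3 and all rows of the chloroplast and mitochondrial genomes. Across genes in those rows, log2(TPM + 1) of WT replicate 1 correlated with the mean of the other libraries at r = 0.055 as deposited and at r = 0.995 when its values were assigned to the identifiers in alphabetical order. In the other 22049 rows r was 0.995. WT replicate 1 was therefore read in alphabetical order of the identifiers. This reading was chosen after seeing the data, and 2 alternatives were run beside it: the column as deposited, and the affected rows of that library treated as missing.

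Genes with a TPM of at least 1 in at least 3 of the 7 libraries were kept, which left 19127 genes. Values were taken as log2(TPM + 1) and compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are glk1 glk2 minus WT on the log2(TPM + 1) scale, which understates the change of low genes. Because TPM values have a fixed sum, the same test was also run after division by trimmed mean of M values (TMM) factors computed on the TPM table (30% trim of log ratios, 5% trim of mean levels). TMM scaling was planned as an alternative. It centres the log ratios left after trimming on 0, and so takes most genes as unchanged between libraries. The rule that "rose" and "fell" are written only of genes called in the same direction with both scalings was set after seeing the data.

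Before the data were examined, 30 gene lists with 441 nuclear genes and the genes of both organelle genomes were fixed. The 27 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), which compares a list with all other genes, with camera using an estimated correlation, and with fry. GLK1, GLK2, FT and CO were also compared by exact two-sided permutation tests over the 35 ways of dividing the libraries into 3 and 4. The genes to name were fixed by rule: GLK1 and GLK2, then the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between groups. The rule added, for each list, up to 4 called members with the largest change, or the member with the smallest p where none was called, and always FT, CO, SOC1, FLC, BBX14, BBX15 and BBX16. Other members of the lists that are named were chosen after their values were seen.

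Alternatives fixed before the data were examined changed the pseudocount, the filter, the scaling, the variance model, the threshold, the set test and the libraries used, with a replicate block among them. The block was fitted without mutant replicate 4, which has no WT library of the same number. Removal of the antenna and photosystem lists, and the repeated fits for genes called with both scalings, were added after seeing the data. The fits were tested on simulated data built from the WT means and the spread of the genes. With 200 of the simulated genes changed in the comparison of glk1 glk2 with WT, and the antenna and photosystem transcripts lowered by their observed amounts under a fixed sum, calls made with both scalings recovered 67.2% of changes of 0.5, 89.6% of changes of 1 and 97.0% of changes of 2 on the log2 scale. Among 18784 unchanged genes they gave 7 false calls higher and 1 lower. In the same simulation 7524 of 18835 unchanged genes were called higher in TPM, against 7 of 18829 after TMM scaling. The simulated spread was drawn separately for each gene and library, so these rates leave out variation that many genes of a library share. The 200 changed genes all had a WT mean of at least 5 TPM, so the recovery rates do not cover lower genes. Most simulated genes were unchanged, as TMM scaling assumes, and the noise was normal on the log2(TPM + 1) scale that limma models. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.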

Results

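The transcriptomes of WT and glk1 glk2 seedlings were compared to find the transcripts that differ when both GOLDEN2-LIKE genes are mutated. GLK1 and GLK2 are GARP-family transcription factors known for promoting chloroplast development and the expression of photosynthesis genes. The 3 WT libraries and the 4 mutant libraries listed 22580 to 22693 genes above 0 TPM. The groups separated on the first principal component, which held 64.4% of the variance. In 65.4% of the genes tested in TPM, and in 23.9% after TMM scaling, the WT and mutant values did not overlap, where chance gives 5.71% without a shift common to all genes. TPM holds such a shift, given below.

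Both targeted transcripts were lower in every mutant library. GLK1 (AT2G20570, TAIR10.1 chromosome 2, positions 8855302 to 8857758) fell from 191 ± 10.4 TPM (SD, n = 3) in WT to 51.7 ± 2.93 TPM (SD, n = 4) in the mutant. GLK2 (AT5G44190, chromosome 5, positions 17798262 to 17800926) fell from 158 ± 2.85 to 50.6 ± 3.49 TPM. The log2 fold changes were -1.86 ± 0.07 (SE, limma adjusted p = 6.975e-07) for GLK1 and -1.63 ± 0.07 (adjusted p = 2.192e-06) for GLK2. The exact permutation p was 0.0286 for each, the smallest that 35 divisions of the libraries allow.

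Transcripts of the light-harvesting antenna and of the photosystems filled 25.7% ± 0.33 (SD, n = 3) of the TPM total in WT and 9.83% ± 0.71 (SD, n = 4) in the mutant. The most abundant transcript was LHCB1.3 in each WT library and RBCS1A, for the small subunit of Rubisco, in each mutant library. In TPM, 12046 of 19127 genes were higher in the mutant and 489 were lower (limma, adjusted p under 0.05), and the median log2 fold change of all tested genes was 0.33. After TMM scaling that median was 0.0099, with 615 genes higher and 964 lower, so that 38.9% of the calls were higher, against 96.1% in TPM. TMM scaling centres most genes near 0, so the median near 0 follows from the method and is no separate finding. With both scalings 615 genes rose and 483 fell, and 0 were called in opposite directions. Asking for both scalings is stricter on falls, as 478 genes were called lower after TMM scaling only and 0 higher after TMM scaling only. The larger number of rises therefore does not show that more genes rose than fell. Below, "rose" and "fell" are used only of genes called in the same direction with both scalings. A list is called higher or lower relative to all other genes. TPM means hold the shift common to most genes, so they show larger rises and smaller falls than TMM scaling does. The number of genes that rose depended on single libraries and on other choices. It was 197, 169 and 322 without WT replicate 1, 2 or 3, and 311 without mutant replicate 1. It was 2663 with array weights, 247 with the replicate block and 199 with WT replicate 1 as deposited.

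**Figure D1:**
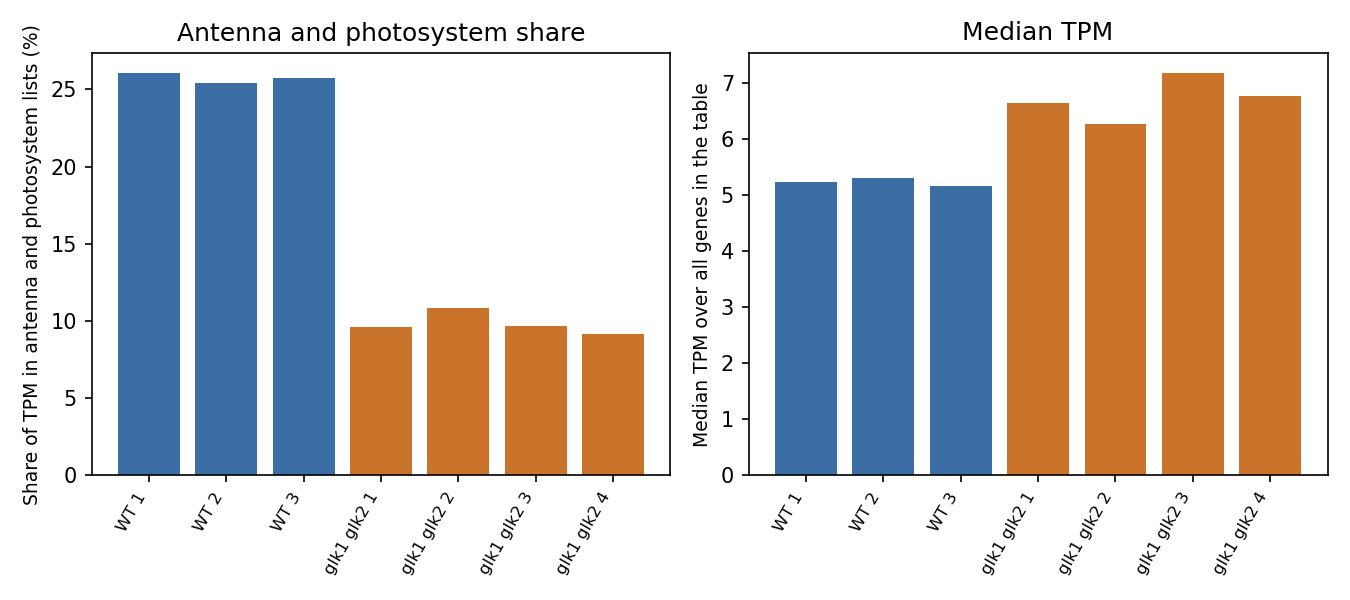
Bars give, for each of the 7 libraries, the share of TPM held by the antenna and photosystem lists (left, percent) and the median TPM over all genes in the table (right). The share is 25.4% to 26.1% in the WT libraries (blue) and 9.15% to 10.8% in the mutant libraries (orange), and the median is 5.15 to 5.30 TPM in WT and 6.26 to 7.17 TPM in the mutant.

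The photosynthetic antenna and photosystem genes fell together. Of the 20 tested genes for light-harvesting chlorophyll-binding proteins, 18 fell and 0 rose. LHCB1.4 fell from 5155 ± 74.2 TPM (SD, n = 3) to 10.4 ± 4.13 TPM (SD, n = 4), LHCB2.3 from 4114 ± 30.5 to 337 ± 54.6 TPM, and LHCB3 from 9334 ± 164 to 2075 ± 207 TPM. All 12 photosystem I subunit genes fell, among them PSAE2, from 1422 ± 36.4 to 377 ± 32.0 TPM, and PSAD2, from 3241 ± 38.1 to 1045 ± 116 TPM. Of 13 photosystem II genes 11 fell, including PSBQ2 of the oxygen-evolving complex, from 2628 ± 24.1 to 733 ± 92.9 TPM. The median log2 fold changes in TPM were -1.59 for the antenna list, -1.21 for photosystem I and -0.61 for photosystem II. All 3 lists were called lower by camera (adjusted p = 4.385e-72, 6.722e-51 and 1.728e-32), and with an estimated correlation (adjusted p = 0.0263, 0.0263 and 0.0334). After TMM scaling the adjusted p with an estimated correlation was 0.164 for each. LHCB1.5 is overlapped by an annotated antisense transcript and has 0 stretches of 50 bases of its own, so its value is uncertain. For LHCB1.1 to LHCB1.4, 78.0% to 89.4% of the stretches occur in no other annotated gene, counting exact matches only. With quantile normalization the call of the photosystem II list was lost (adjusted p = 0.0551).

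Of 26 genes for making chlorophyll, 17 fell and 0 rose. PORB, a light-dependent protochlorophyllide oxidoreductase, fell from 431 ± 30.7 TPM (SD, n = 3) to 80.1 ± 18.3 TPM (SD, n = 4). PORA, its paralog, fell from 5.01 ± 0.97 to 0.10 ± 0.084 TPM. CAO, which makes chlorophyll b, fell from 344 ± 11 to 118 ± 6.76 TPM, and HEME1, a uroporphyrinogen decarboxylase, from 107 ± 12.0 to 42.0 ± 1.26 TPM. The list was called lower (camera adjusted p = 3.930e-38), with adjusted p = 0.0532 with an estimated correlation. Among 16 carotenoid genes, PSY, which encodes phytoene synthase, fell from 191 ± 11.2 to 109 ± 7.99 TPM and BCH2, a beta-carotene hydroxylase, from 43.5 ± 1.83 to 20.7 ± 3.32 TPM. ZDS, zeta-carotene desaturase, rose from 89.6 ± 7.52 to 147 ± 11.7 TPM. The log2 fold change of ZDS was 0.71 in TPM and 0.35 after TMM scaling (TMM-scaled limma adjusted p = 0.0462). That list was not called (camera adjusted p = 0.965). Limma called 12 of the 16 genes higher and 2 lower in TPM, and 1 higher and 3 lower after TMM scaling.

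**Figure D2:**
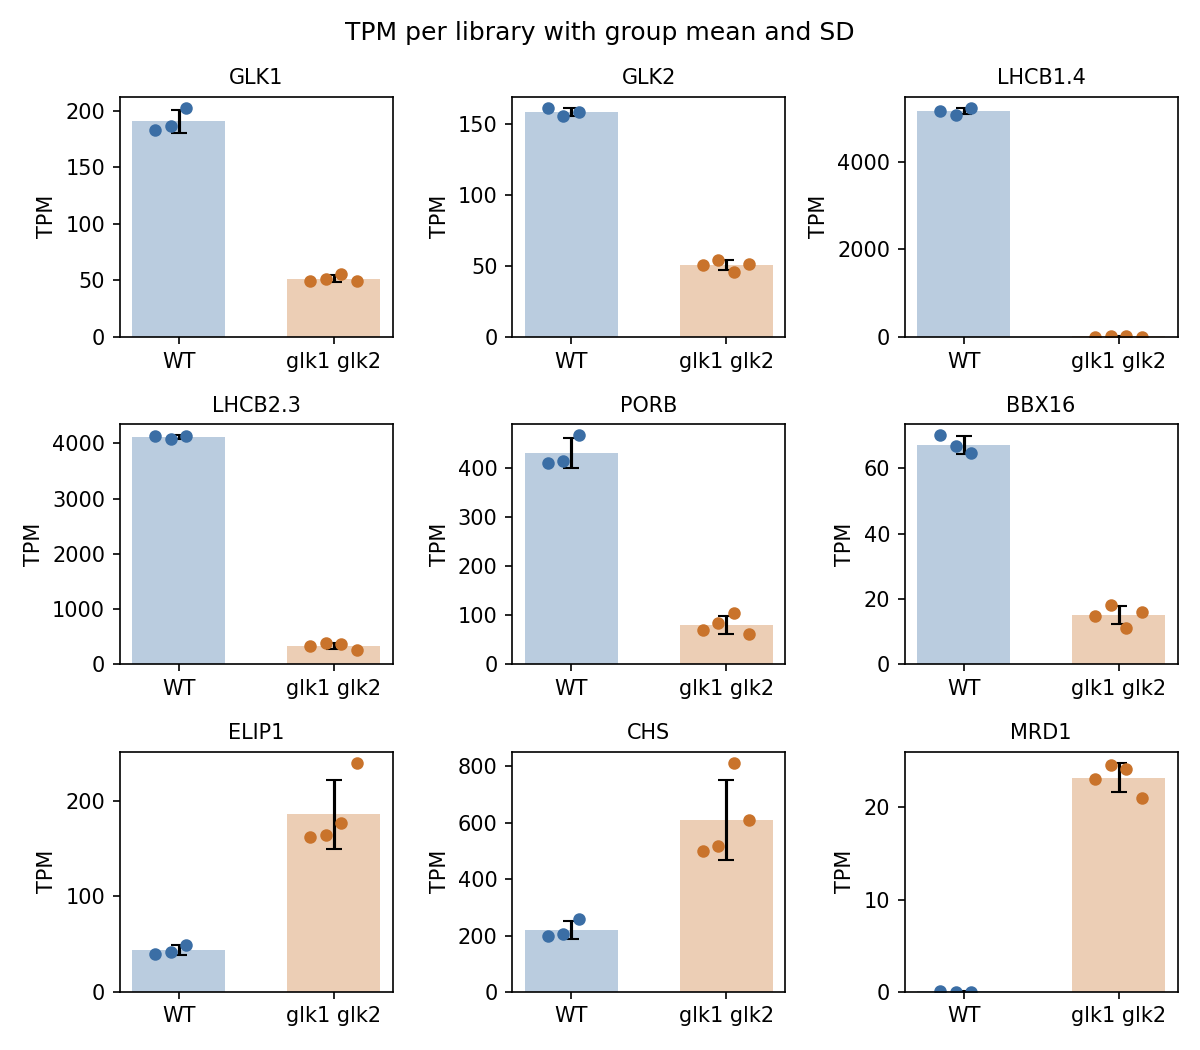
Points are the TPM of single libraries of WT (blue, n = 3) and glk1 glk2 (orange, n = 4), bars are group means and error bars are SD, on linear axes from 0. In each of the 9 genes drawn the 2 groups do not overlap, with GLK1, GLK2, LHCB1.4, LHCB2.3, PORB and BBX16 lower and ELIP1, CHS and MRD1 higher in the mutant.

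Of 19 Calvin cycle genes, which encode enzymes of carbon fixation, 2 fell and 0 rose: GAPA2, a subunit of plastid glyceraldehyde-3-phosphate dehydrogenase, from 1180 ± 105 TPM (SD, n = 3) to 835 ± 49.8 TPM (SD, n = 4), and RBCS3B, from 11947 ± 921 to 9332 ± 713 TPM. The call of RBCS3B was lost without WT replicate 2 (limma adjusted p = 0.0704), WT replicate 3 (0.0956) or mutant replicate 1 (0.0513), without a filter (0.192) or with the replicate block (0.0904), and with quantile normalization its log2 fold change was 0.24 (0.295). Limma called 6 of the 19 Calvin cycle genes higher and 2 lower in TPM, and 0 higher and 5 lower after TMM scaling. The list was called lower relative to other genes (camera adjusted p = 0.0019, and adjusted p = 0.611 with an estimated correlation), although its median log2 fold change in TPM was 0.14. The call was lost without mutant replicate 3 (camera adjusted p = 0.104) and with array weights (0.0864), and with quantile normalization the list was called in the opposite direction, higher (0.0027). None of 11 photorespiration genes changed with both scalings in limma (6 called in TPM and 1 after TMM scaling, 6 and 4 at an unadjusted p under 0.05), and the list was not called (camera adjusted p = 0.975), but was called higher with quantile normalization (0.0451). Of 18 genes of the plastid transcription machinery, SIG1, a sigma factor, fell from a mean of 100 to 83.8 TPM and 0 rose (list camera adjusted p = 0.975). Limma called 13 of the 18 higher and 1 lower in TPM, and 0 higher and 1 lower after TMM scaling. Of 71 tested genes of the chloroplast genome, ATCG00050 fell, from 1.47 ± 0.30 to 0.55 ± 0.36 TPM, and 0 rose. That list was called lower (adjusted p = 6.524e-07), with adjusted p = 0.432 with an estimated correlation and a median log2 fold change in TPM of 0.23. The call was lost after TMM scaling (adjusted p = 0.114) and with quantile normalization (0.563). Chloroplast genes held 1.39% ± 0.14 (SD, n = 3) of TPM in WT and 1.57% ± 0.23 (SD, n = 4) in the mutant. Mitochondrial genes held only 0.0050% to 0.0068% in each library. How well the libraries capture organelle transcripts was not assessed. None of the 12 tested mitochondrial genes changed with both scalings in limma (2 called in TPM and 0 after TMM scaling, 3 and 2 at an unadjusted p under 0.05). Their list was not called (camera adjusted p = 0.0794), but was called lower without a filter (5.930e-10), with WT replicate 1 as deposited (9.024e-05), and without WT replicate 2 (0.0262), mutant replicate 1 (0.0487) or mutant replicate 2 (0.0452).

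The largest falls outside photosynthesis were in genes of varied or unknown function. AT3G55240 fell from 53.6 ± 0.33 TPM (SD, n = 3) to 0.26 ± 0.25 TPM (SD, n = 4), AT1G14250, of the nucleoside phosphatase family, from 78.1 ± 9.87 to 0.88 ± 0.15 TPM, and AT3G01345 from 63.6 ± 6.31 to 0.58 ± 0.094 TPM. The other genes with the largest falls were AT1G13650, PGL5, AT5G48490, AT4G13575, AT1G77960, AT5G03350 and PDF1.2c, with log2 fold changes of -5.25 to -2.78. The defensin gene PDF1.2c had 34.9 TPM in WT replicate 1 against 7.39 and 3.21 TPM in the other WT libraries, and its log2 fold change was -1.91 without WT replicate 1 (limma adjusted p = 0.0074) and -3.46 without WT replicate 3 (0.0036). The largest rise was in MRD1, from 0.047 ± 0.050 to 23.2 ± 1.59 TPM, a log2 fold change of 4.53 ± 0.09 (SE, limma adjusted p = 1.866e-08). ELIP2 and ELIP1, early light-induced chlorophyll-binding proteins, rose from 15.2 ± 4.93 to 82.9 ± 29.8 TPM and from 43.7 ± 5.19 to 186 ± 36.6 TPM. AT5G55450, TCL1, CWINV5, AT3G22142, HEI10, AT1G51090, AT2G41090 and ACD6 rose with log2 fold changes of 1.63 to 2.12 in TPM. The TMM-scaled limma adjusted p of AT3G22142 was 0.0371. PAP2, a MYB regulator of anthocyanin synthesis, had 1.74 ± 0.41 TPM in WT and 12.1 ± 12.5 TPM in the mutant and was not called after TMM scaling (limma adjusted p = 0.125).

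Among 22 tested B-box genes, which encode zinc-finger regulators of light responses and flowering, 7 fell and 2 rose. BBX16 fell from 67.2 ± 2.73 TPM (SD, n = 3) to 15.1 ± 2.88 TPM (SD, n = 4), BBX14 from 54.4 ± 1.5 to 24.2 ± 2.67 TPM, COL2 from 71.4 ± 4.45 to 33.4 ± 3.32 TPM, and BBX15 from 157 ± 9.79 to 129 ± 9.25 TPM. BBX17, COL1 and COL4 also fell. BBX18 rose from 40.3 ± 2.36 to 79.1 ± 2.88 TPM, and BBX22 from a mean of 32.5 to 61.6 TPM. The list was called lower relative to other genes (camera adjusted p = 1.375e-05, and adjusted p = 0.133 with an estimated correlation), with a median log2 fold change in TPM of 0.22 and a mean of -0.029. Of 15 regulators of greening, the GATA factor GNC rose, from 28.8 ± 3.19 to 51.1 ± 3.88 TPM, and the blue-light receptor gene CRY1 fell, from a mean of 106 to 90.08 TPM. The log2 fold change of GNC was 0.81 in TPM and 0.46 after TMM scaling. After TMM scaling limma called 6 of the 15 lower and 1 higher, against 1 lower and 8 higher in TPM. The greening list lay lower after TMM scaling, without a call (camera adjusted p = 0.0501). HY5 had 9.25 ± 1.00 TPM in WT and 14.9 ± 0.84 TPM in the mutant, with a TMM-scaled adjusted p of 0.0894.

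Of 24 tested flowering-time genes 1 rose and 1 fell, where limma called 13 higher and 1 lower in TPM, and 14 in TPM and 7 after TMM scaling had an unadjusted p under 0.05. CDF3, a DOF-type regulator, rose from 106 ± 5.10 TPM (SD, n = 3) to 165 ± 8.52 TPM (SD, n = 4). The log2 fold change of CDF3 was 0.63 in TPM and 0.27 after TMM scaling (TMM-scaled limma adjusted p = 0.0276). FLC, a repressor of flowering, fell from 8.73 ± 1.4 to 5.55 ± 1.5 TPM. The call of FLC was lost without WT replicate 2 (log2 fold change -0.48, limma adjusted p = 0.0897). With WT replicate 1 as deposited the calls of FLC (0.0593) and CDF3 (0.141) were both lost. FT, the mobile flowering signal, had 0.59 ± 0.15 TPM in WT and 0.59 ± 0.20 TPM in the mutant, and its activator CO had 0.27 ± 0.046 and 0.28 ± 0.054 TPM. Both lay under the filter, and exact permutation tests gave p = 1 for FT and p = 0.886 for CO. These values hold for ZT4, the only time sampled, and other times of day were not assessed. SOC1 had 47.6 ± 0.75 and 61.6 ± 3.76 TPM, a log2 fold change of 0.36 in TPM and 0.0083 after TMM scaling. None of 17 circadian clock genes changed with both scalings in limma (14 called in TPM and 0 after TMM scaling, 14 and 5 at an unadjusted p under 0.05). Neither the flowering list (camera adjusted p = 0.329) nor the clock list (0.421) was called, nor were the greening regulators (0.0842), which were called lower with a mean of at least 5 TPM (0.0220), with quantile normalization (0.0451), without the photosystem and antenna lists (0.0423), and without mutant replicate 1 (0.0487) or 3 (0.0432).

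Of 23 tested flavonoid genes, 6 rose and 0 fell. CHS, which encodes chalcone synthase at the entry to the pathway, rose from 220 ± 32.8 TPM (SD, n = 3) to 610 ± 143 TPM (SD, n = 4), and F3H from 56.5 ± 3.73 to 134 ± 25.2 TPM. CHI, FLS1, PAL1 and 4CL3 rose as well. The list was not called in TPM (camera adjusted p = 0.114) and was called higher after TMM scaling (adjusted p = 4.948e-07, and adjusted p = 0.481 with an estimated correlation). It was also called higher with quantile normalization (1.206e-06), without the photosystem and antenna lists (8.756e-05), with the replicate block (4.404e-04), without a filter (0.0346), and without WT replicate 3 (0.0489), mutant replicate 1 (0.0216) or mutant replicate 3 (0.0432). In the oxidative and plastid stress list of 10 genes, ELIP1 and ELIP2 rose and 0 fell (camera adjusted p = 0.421). Of 12 cold-response genes, KIN1 rose from 56.1 ± 1.92 to 116 ± 18.4 TPM, RD29A from 27.2 ± 0.61 to 56.3 ± 7.59 TPM, and ERD10 from a mean of 94.4 to 168 TPM. COR413IM1 fell from 51.0 ± 1.11 to 25.1 ± 3.38 TPM and COR15B from 4.50 ± 0.49 to 2.04 ± 0.62 TPM, and the list was not called (adjusted p = 0.589). None of 4 tested heat shock genes, too few for a list test, changed with both scalings in limma (2 called in TPM and 0 after TMM scaling, 2 and 0 at an unadjusted p under 0.05).

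Of 18 glucosinolate genes, 11 fell and 0 rose, where limma called 14 lower and 0 higher after TMM scaling. BCAT4, MAM1 and CYP79F1, of the methionine-derived branch, fell from 155 ± 12.4 TPM (SD, n = 3) to 68.0 ± 25.9 TPM (SD, n = 4), from 217 ± 21.8 to 103 ± 27.6 TPM, and from 67.8 ± 9.80 to 30.1 ± 9.54 TPM. The list was called lower (camera adjusted p = 5.177e-27), with adjusted p = 0.103 with an estimated correlation. Of 12 genes induced by sugar starvation, 4 fell and 0 rose, where limma called 8 lower and 0 higher after TMM scaling. DIN6, an asparagine synthetase gene induced in the dark, fell from 51.6 ± 6.92 to 9.18 ± 1.34 TPM, TPS11 from 33.3 ± 2.42 to 22.0 ± 3.34 TPM, TPS8 from 47.5 ± 2.28 to 34.9 ± 1.31 TPM, and DIN4 from a mean of 19.2 to 16.2 TPM. This list was called lower (adjusted p = 1.567e-12), with adjusted p = 0.0784 with an estimated correlation.

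Defence and iron genes went both ways. Of 17 salicylic acid genes, ICS1, which encodes isochorismate synthase, fell from 12.5 ± 0.24 TPM (SD, n = 3) to 4.21 ± 0.96 TPM (SD, n = 4), while WRKY33 rose from 14.9 ± 1.33 to 26.8 ± 3.76 TPM and PBS3 from 1.14 ± 0.20 to 2.68 ± 0.40 TPM (list camera adjusted p = 0.232). The list was called lower with a mean of at least 5 TPM (0.0467) and with array weights (0.0394). The TMM-scaled limma adjusted p was 0.0298 for WRKY33 and 0.0331 for PBS3. Of 15 jasmonate genes, LOX2, a lipoxygenase of jasmonate synthesis, rose from 136 ± 25.9 to 335 ± 73.3 TPM. The defensin gene PDF1.2A fell from 29.7 ± 26.6 to 3.85 ± 1.74 TPM. WT replicate 1 had 60.3 TPM of PDF1.2A against 16.0 and 12.7 TPM in the other WT libraries, and without it the log2 fold change was -1.72 (limma adjusted p = 0.0040). The jasmonate list was called lower (camera adjusted p = 3.754e-04, and adjusted p = 0.165 with an estimated correlation), with a median log2 fold change in TPM of 0.14 and a mean of -0.091. Of 11 iron genes, the ferritin gene FER1 rose from 312 ± 47.1 to 677 ± 185 TPM and IMA2, an iron-uptake peptide gene, fell from 1.39 ± 0.28 to 0.56 ± 0.26 TPM. The rise of FER1 was close to the threshold after TMM scaling (TMM-scaled limma adjusted p = 0.0485). The iron list was called lower (adjusted p = 0.0093, and adjusted p = 0.358 with an estimated correlation), with a median of 0.21. The call was lost after TMM scaling (camera adjusted p = 0.131), with quantile normalization (0.109), with a mean of at least 5 TPM (0.465), without the photosystem and antenna lists (0.0901), and without WT replicate 1, 2 or 3 (0.137, 0.0634 and 0.0757).

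Of 22 root marker genes, SULTR1;1, a sulfate transporter, rose from 0.42 ± 0.091 TPM (SD, n = 3) to 2.08 ± 0.80 TPM (SD, n = 4), and 0 fell. The list was not called (camera adjusted p = 0.118), but was called lower with array weights (0.0457) and without WT replicate 3 (0.0047) or mutant replicate 4 (0.0338). None of 12 epidermis and stomata genes (0.965), 12 vascular genes, 8 seed storage genes or 1 tested floral gene changed with both scalings in limma. At an unadjusted p under 0.05 the counts in TPM and after TMM scaling were 7 and 1 for epidermis, 3 and 1 for vascular genes, 0 and 0 for seed storage, and 0 and 1 for the floral gene, SEP3. The vascular list was called lower (adjusted p = 0.0205, and adjusted p = 0.611 with an estimated correlation) with a median of 0.17. Its call was lost after TMM scaling (adjusted p = 0.0837), with quantile normalization (0.0758), without a filter (0.133), with the replicate block (0.187), with WT replicate 1 as deposited (0.0645), without the photosystem and antenna lists (0.0581), without WT replicate 2 (0.0634) and without mutant replicate 4 (0.132). The seed storage list was also called lower (adjusted p = 0.0028, and adjusted p = 0.578 with an estimated correlation) although its median was 0.67. Its direction turned to higher, with no call, after TMM scaling (adjusted p = 0.883), with quantile normalization (0.960) and with the replicate block (0.140), and the call was lost without the photosystem and antenna lists (0.735) and without WT replicate 2 (0.0979). Summed seed storage transcripts were 220 TPM in WT replicate 2 and 1039 TPM in mutant replicate 2, against 1.65 to 38.9 TPM in the other libraries. All 10 housekeeping genes were higher in TPM, with a median log2 fold change of 0.39, and 0 were called after TMM scaling (0 at an unadjusted p under 0.05), where the median was 0.042. The housekeeping list was not called (camera adjusted p = 0.0660), but was called higher without a filter (0.0134), with quantile normalization (0.0460) and with WT replicate 1 as deposited (0.0475). ACT2, for example, had 323 ± 18 and 462 ± 32 TPM. TMM scaling removes a shift common to most genes, so the lack of calls does not show unchanged transcript amounts.

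**Figure D3:**
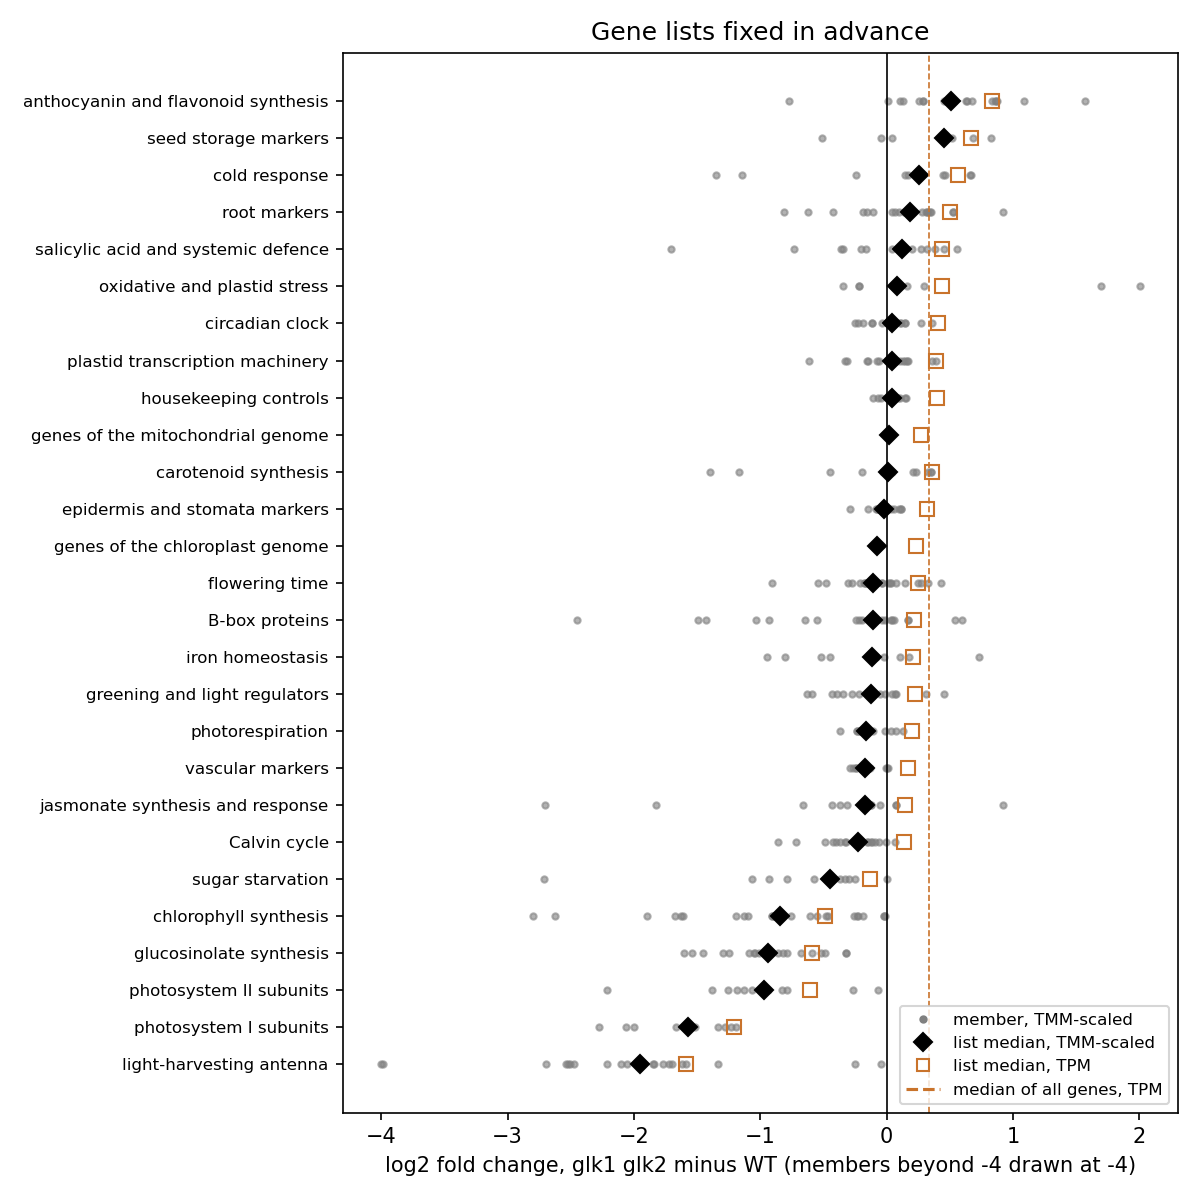
The log2 fold change of glk1 glk2 minus WT is drawn for each tested gene list, with grey points for members after TMM scaling (LHCB1.4, beyond -4, is drawn at -4), black diamonds for list medians after TMM scaling, orange squares for list medians in TPM and a dashed line for the TPM median of all tested genes (0.33). The chloroplast and mitochondrial genome lists are drawn as medians only, and the antenna and photosystem medians lie farthest to the left.

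In all, camera called 13 of the 27 lists tested in TPM and 10 after TMM scaling, 9 of them with both and in the same direction. With an estimated correlation 3 were called in TPM (the antenna and both photosystem lists) and 0 after TMM scaling. Fry, which does not compare a list with other genes, called 18 lists in TPM and 8 after TMM scaling. In 21 of the 30 lists the TPM calls counted were the same when adjusted over the list alone as over all genes tested. In the other 9 they differed, most in the chloroplast genome list, where 19 genes higher and 2 lower became 0 adjusted over the list alone.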

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

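The test of whether the whole LHCB1 family fell alike, and the tests on the column of WT replicate 1, were chosen only after the result was seen. Among 132 values examined over the 4 mutant libraries, 7 had 1 library far from the other 3, and chance alone flags about 1 in 20. Mutant replicate 3 had 13.7 TPM of HY5 (15.3 to 15.5 in the other mutant libraries), 76.7 TPM of UGT75C1 (23.6 to 30.6), 0.94 TPM of PDF1.2B (0 to 0.080) and 444 TPM of LOX2 (284 to 309). Mutant replicate 2 had 2877 TPM of PSBP1 (2505 to 2556) and 203 TPM of the seed storage gene SESA4 (0.43 to 1.04). Mutant replicate 4 had 144 TPM of KIN1 (104 to 110).

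LHCB1.4 was nearly absent in the mutant, at 10.4 TPM against 5155 TPM in WT. Reads lost to paralogs of identical sequence are argued against, since 86.3% of the 50-base stretches of its transcript occur in no other annotated gene. Only exact matches were counted, so stretches that differ slightly from a paralog were not judged. The values also argue against a deletion reaching AT2G34450, a nearest tested gene, which was at 145% or more of its WT mean in the mutant libraries. LHCB1.5, the nearest tested gene on the other side, was at 30.3% of its WT mean or more. It has 0 stretches of its own, so a deletion on that side is less well judged. Genes in between that were not tested were not examined. A loss of GLK activity that acts on the LHCB1 family alike is also argued against, because LHCB1.4 lay 6.56 below the LHCB1 gene that fell next most, on the log2 scale. A change in LHCB1.4 alone in the mutant line, or a stronger dependence of this gene on GLK activity, stays open and was not tested.

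Most genes were higher in the mutant in TPM. Removing the antenna and photosystem lists and rescaling lowered the median log2 fold change by 0.247, from 0.33 to 0.086. The size of that drop is set by the shares of TPM that the lists held in WT and mutant, so it is no separate evidence. It gives the part of the shift that those shares account for under a fixed TPM total. Removing the organelle genes did not lower the median (a fall of -0.0029, that is, a rise to 0.336), which argues against them. A rise in total RNA per cell would not be visible in TPM, and no biological explanation was tested.

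WT replicate 1 was unlike the other libraries in 5606 rows as deposited. Read in alphabetical order of the identifiers it correlated with the mean of the others at 0.995 in those rows, against 0.055 as deposited, which is consistent with a column sorted apart from its identifiers. A degraded library is argued against by the rows where both orders agree, in which its lower correlation with the other WT libraries was 0.995 and theirs with each other was 0.996. Those correlations say little on the genotype, since in these rows each library correlated at 0.993 to 0.997 with a mean over both genotypes. A swapped genotype is argued against by GLK1, at 183 TPM in WT replicate 1, 187 and 203 TPM in the other WT libraries and 49.7 to 56.0 TPM in the mutant.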

How the results depend on the processing

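Alternatives that read WT replicate 1 in another way, remove the photosystem and antenna lists, or repeat the counts of genes called with both scalings, and the comparison of the genes of 2 divisions, were chosen only after the result was seen. GLK1 and GLK2 kept direction and call under each alternative run. The counts in TPM followed the scaling, with a median log2 fold change of 0.0099 with TMM, 0.021 with quantile normalization and 0.086 without the photosystem and antenna lists, against 0.33: 1579 genes changed (615 higher, 964 lower) with TMM, 1684 (762 and 922) with quantile normalization, and 2211 (1482 higher) without the photosystem and antenna lists. TMM scaling and quantile normalization both centre most genes near 0, so their medians near 0 follow from the method. With an absolute log2 fold change of at least 1 in TPM, 227 genes changed, 108 higher and 119 lower. Camera with an estimated correlation called 3 lists. Genes higher with both scalings numbered 2663 with array weights, 247 with the replicate block and 199 with WT replicate 1 as deposited, and the cause was not tested. They ranged from 169 to 765 when 1 library was left out, with 168 to 527 of the 615 genes kept, and genes lower with both scalings from 353 to 572. With WT replicate 1 as deposited 9480 genes were changed in TPM, and 198 of the 615 and 327 of the 483 genes were kept. Of 126 named genes 26 then lost their call, among them LHCB2.3 (limma adjusted p = 0.510), HEME1 (0.992), LOX2 (0.141) and F3H (0.0539), and 5 more turned direction. Of 125 named genes tested with TMM, 46 lost their call and 5 more lost it with a turned direction. With a library left out, named genes were followed in the TPM fit only, so their calls after TMM scaling were not checked that way. Of the named genes 8 fell under the filter whenever a WT library was left out, since they reach 1 TPM in WT libraries only. Variance models without the trend or robust were not run for the lists, as camera estimates its own variances. Depth is unknown, so what it limits for low genes such as FT and CO was not assessed.

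Whether replicate numbers pair the libraries is not given in the labels and is left open. Deviations of each library from its group mean were correlated across genes. WT replicates 2 and 3 correlated best with the mutant library of the same number (0.171 and 0.155). For WT replicate 3 the value with mutant replicate 1 was close, at 0.144. Seed storage transcripts were highest in replicate 2 of both groups. WT replicate 1, however, correlated best with mutant replicate 4 (0.275, against -0.096 with mutant replicate 1). The replicate block, which also leaves out mutant replicate 4, left 11460 genes changed, 10999 higher and 461 lower, with 12 lists called.

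Directions that reversed are given next, as camera adjusted p for lists and log2 fold change for genes; the cause was not tested. With TMM these were salicylic acid (0.670), cold (0.131), root (0.347), seed storage (0.883) and epidermis (0.883), and RBCS1B (-0.0073), GGT1 (-0.011), FER4 (-0.021), CESA7 (-0.0054) and ATMG00030 (-0.086). With quantile normalization they were Calvin cycle (0.0027) and photorespiration (0.0451), both called higher, carotenoid (0.967), salicylic acid (0.888), cold (0.133), root (0.280), seed storage (0.960), epidermis (0.967) and the mitochondrial genome (0.967), and PSBP1 (0.053), PSBW (0.047), RBCS3B (0.24), FER4 (-0.011), CESA7 (-0.0037) and ATMG00030 (-0.092). Without a filter they were photorespiration (0.462), carotenoid (0.468) and plastid transcription (0.462). With array weights they were photorespiration (0.533), carotenoid (0.919), plastid transcription (0.632) and SESA4 (-0.34), and with the replicate block seed storage (0.140). Without the photosystem and antenna lists they were salicylic acid (0.986), cold (0.429), root (0.882), epidermis (0.986) and ATMG00030 (-0.0073). With WT replicate 1 as deposited they were epidermis (0.957), PSBTN (1.89), PAD4 (-0.25), BCAT4 (0.25), ATCG00330 (1.60) and ATMG00520 (-0.66). Leaving out 1 library gave, each with a reversal in at least 1 case, epidermis 0.564 to 0.987, photorespiration 0.608 to 0.909, carotenoid 0.688 to 0.988, plastid transcription 0.329 to 0.975 and SESA4 -0.48 to 1.90.

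Over the 35 divisions of the libraries into 3 and 4, 1 gave as many changed genes (12535, next 4486) and 1 as many higher (12046, next 179). With both scalings, 1 gave as many higher (615, next 2) and 1 as many lower (483, next 0). In each case that was the real grouping, and 0.0286 is the smallest permutation p that 35 divisions allow. Each other division mixes the genotypes in a group, which widens the spread and lowers its counts, so chance is not excluded. For genes lower in TPM 2 divisions gave at least 489, so that count alone does not speak against chance. The other division, mutant replicates 1, 3 and 4 against the rest, gave 4307, of which 4122 were higher in the mutant in the real grouping. It gave 0 with TMM, so it holds the shift in TPM with its sign turned. Of the 489 genes, 483 are also lower with TMM. The number of lists called does not speak against chance, since 18 divisions gave at least 13, the highest other 17.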

Other observations

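The test on runs of adjacent genes was chosen only after the result was seen, and the 7 gene families below were chosen after the data were examined. Relative to other genes, NDH complex genes (26 tested, 4 fell), histone genes (42 tested, 2 fell) and SAUR-like auxin-responsive genes (57 tested, 3 fell) were lower with both scalings, with 0 that rose in each. The histone genes that fell were HIS1-3 and HTA4, and HTA4 lies in the run of adjacent genes on chromosome 4 described below. The larger of the camera adjusted p of the scalings was 8.974e-04, 7.849e-05 and 3.901e-06. With an estimated correlation the adjusted p was 0.442, 0.155 and 0.155 in TPM, and 0.497, 0.269 and 0.289 after TMM scaling. The median log2 fold changes of the families in TPM were above 0, at 0.17, 0.13 and 0.075. Among the genes of these families NdhS fell from 328 ± 3.62 TPM (SD, n = 3) to 257 ± 17 TPM (SD, n = 4) and SAUR22 from 8.39 ± 1.71 to 5.20 ± 0.90 TPM. Cytosolic ribosomal protein genes (16 tested, larger camera adjusted p 0.637), pentatricopeptide repeat genes (184 tested, 0.691), cytochrome P450 genes (147 tested, 0.108) and the chloroplast import translocon (20 tested, 0.320) were not called with both scalings. With a single scaling, camera called the ribosomal protein genes lower after TMM scaling (adjusted p = 0.0315) and the P450 genes lower in TPM (7.849e-05). Families were picked by words in gene names or products, so members named otherwise are missing. In the P450 family 12 of 147 genes fell and 7 rose, and CYP81D11 fell from 42.4 ± 2.70 to 5.98 ± 1.75 TPM.

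Some genes that changed over 2-fold with both scalings lie side by side in the order of tested genes, where untested genes may lie between them. Of 141 genes changed over 2-fold, 13 pairs were adjacent and in the same direction (permutation p = 0.0001 over 10000 random draws, the smallest they can give, with at most 5 pairs in a draw). The draws ignore that paralogs and overlapping genes lie together, so this p does not separate such pairs from other causes. The longest run held 5 genes, against at most 3 in a draw. It lies on chromosome 4, where UNE15 (2.67 ± 0.26 TPM in WT, n = 3), HTA4 (3.0 ± 0.60), AT4G13572 (2.78 ± 0.24), AT4G13575 (13.6 ± 0.69) and AT4G13577 (2.38 ± 0.41) had at most 0.25 TPM in any mutant library (n = 4), and AT4G13577 is listed at 0 in each. A candidate explanation is a deleted, silenced or differing stretch of chromosome in the mutant line, separate from GLK activity, which the reads would have to decide. MRD1 and its neighbour HEI10, with 0.94 ± 0.067 TPM in WT and 5.41 ± 1.06 TPM in the mutant, form another such pair that rose. AT5G35480 and MRU1 form a pair that fell, from 6.34 ± 0.84 to 2.36 ± 1.22 TPM and from 7.60 ± 0.69 to 1.47 ± 0.74 TPM. The other runs are LHCB1, LHCB2 and defensin paralogs, or photosystem genes beside AT1G55673 and AT4G28755, where reads may be shared. A narrower test decided nothing: among the 15 genes at 5 TPM or more in 1 genotype and at 10% of that level or less in the other, 0 pairs lay within 5 tested genes of each other, but random draws also had a median of 0, so the bound set for it could not be undercut.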
